A study of Aspergillus nidulans with 7 samples.

How the data were processed

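Transcript levels were measured by mRNA sequencing in Aspergillus nidulans FGSC A4, a wild-type reference strain of this filamentous fungus, while it formed conidia, its asexual spores. Per the labels' protocols, spores were grown as an aerated submerged culture, the mycelium was collected on filter paper, the 0 h filters were frozen at once, and the other filters were kept moist and exposed to air under constant light until 6, 12, 18, 24, 30 or 48 h. Per the labels' protocols, duplicate filters were taken at each time and libraries were made with an Illumina mRNA kit. The deposited table gives 1 column of each unit per time, and whether the filters of a time were pooled is not given in the sources used here. Each of the 7 libraries was placed at its time by its label. The series' design text says that the raw reads no longer exist, so nothing upstream of the deposited values could be rerun.

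The deposited table lists 10639 genes on 226 contigs. Per the file headers, the authors gave each gene in each library a count, a signal in reads per nucleotide and an RPKM value. The counts deposited by the authors were whole numbers that had not been normalized, and they were the values tested here. The RPKM values deposited by the authors used as denominator the sum of the same column's counts in all 7 libraries, and the signal in reads per nucleotide deposited by the authors carried no further scaling. Neither of those was tested. CASAVA is named in the submitters' processing notes, without a version or a role. The aligner, the genome build, the annotation, the strand setting and the treatment of reads that fit several places are not given in the sources used here, so overlapping or antisense genes and near-identical paralogs cannot be separated in these counts. Contig positions are printed as the deposited table gives them, on a build that is not given in the sources used here. All 21 columns of values belonged to a labelled sample.

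Symbols came from a table of the ASM1142v1 reference, used for names only. It held 10455 of the 10639 identifiers, and 778 of these had a symbol. No count was recorded in any library for 228 genes. The reference table gave no product text, so the planned lists by product text could not be built.

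The slope on hours was tested for each gene with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fits) after TMM normalization. Genes needed a CPM of at least 1 in at least 1 library and at least 15 counts in all. The 0 to 48 h fit used all 7 libraries and the 6 to 48 h fit left out the submerged culture. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05, and fitted changes are slopes multiplied by the hours spanned, on the log2 scale, with their standard errors. With 1 library per time, no time could be tested against another, and every departure from a straight line counts as error. A curve with hours and hours squared was tested by the F test of the same tool. Neighbouring times were compared by size alone: TMM-normalized CPM plus 0.5 had to differ at least 4-fold, with at least 10 CPM in the higher library. These pairs have no replicate check. Fold intervals are exact 95% limits from the counts of both libraries, and they cover counting error only. Where a library had no count, a bound against 3 counts in that library is given as "at least". Lists were tested with camera on limma-voom values (limma 3.58.1) with a preset correlation between genes of 0.01, with camera and an estimated correlation, and with fry, each adjusted over 24 lists. For 6 h against 0 h, each list's median was placed among 10000 random lists matched on mean level. The genes of these random lists were drawn independently, so the percentiles do not allow for genes that move together or for variation between libraries. DESeq2 1.42.0 gave the alternative test. Tables and plots were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

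The TMM factor was 0.459 at 0 h and rose through 0.878, 1.042, 1.071, 1.216 and 1.311 to 1.395 at 48 h, while the 100 most abundant genes held 45.3% of the counts at 0 h and 20.8% at 48 h. Against scaling by totals, TMM moved all genes by 1.12 log2 units at 0 h and by -0.48 at 48 h. The median fitted change over 0 to 48 h was 0.11 with TMM, 0.41 with upper quartile factors and 1.35 with totals alone, so every rise or fall reported here is relative to the bulk of genes.

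On simulated counts with the real libraries' means and sizes, the 0 to 48 h slope test covered 9556 genes. It recovered 42% of genes with a change of 2 log2 units and 100% of those with a change of 4, with 6 false among 148 calls and 0 calls when no gene was changed. For the 6 to 48 h test over 9538 genes these shares were 55% and 100%, with 9 false among 164 calls and 0 calls when no gene was changed. The curve test recovered 76% and 100% of simulated peaks of these heights over 9566 genes, with 6 false calls. Those peaks had the shape of the fitted curve, so sharper peaks were not covered. Apart from the changed genes, all simulated libraries had the same composition, with a fixed dispersion of 0.1. Larger dispersions, and shifts in composition like those behind the real TMM factors, were thus not covered either.

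The groups, tests, alternatives, naming rule and 12 gene lists were set before the data were examined. Another 12 lists were built from the reference symbols once the table of names had been seen and before any level of their genes was looked at; these are the lists of proteasome, ergosterol synthesis, iron and siderophores, nitrate and proline use, ribosome assembly, mitochondrial protein import, peroxins, autophagy, plant polysaccharide degradation, glucan and cell wall remodelling, heat shock proteins and nuclear migration. The earlier 12 covered central conidiation regulators, upstream activators, repressors, conidial pigment and spore wall, conidial stress tolerance, the sterigmatocystin cluster, sexual development, light receptors, chitin synthases, autolysis, low oxygen and C2 metabolism, and the cell cycle with septins. A member was left out where the reference gave its identifier another name, which removed wA, fadA, pkaA, gprA, gprB, chsC, csmA and pepJ, or where it had no identifier in the table, which removed tmpB, conF and AN7813. Symbols were matched to the reference first. It placed chsA, chsB, chsD and nimE at AN4566, AN7032, AN1046 and AN3648, which were not the identifiers set beforehand for these symbols.

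Named genes are the members of the regulator, activator, repressor, pigment, stress, light and low oxygen lists, the 10 with the largest fitted change per direction and slope test among those past the test with at least 10 CPM in their highest library, the 10 largest folds per direction between 0 h and 6 h, and for each time the 3 genes highest over their own mean elsewhere with at least 50 CPM. As most genes have no symbol, each ranking was drawn for genes with a symbol as well as for all genes, and at most 2 genes per direction are given by identifier in a comparison. Genes chosen otherwise are marked as such where they appear.

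The alternatives tried were other normalizations, count filters, tests, time scales, fold limits and pseudocounts, and the omission of each library in turn. Scaling by totals alone in the slope and list tests was added after the data had been seen.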

Results

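The data were 7 mRNA sequencing libraries of Aspergillus nidulans, 1 each at 0 h, at every 6 h up to 30 h, and at 48 h after mycelium from a submerged culture was exposed to air. By the labels' account the times span the growth of aerial hyphae (about 6 h), the forming of vesicles and metulae (by about 12 h), phialides (12 to 18 h) and, from 24 to 48 h, mature conidiophores with chains of spores. Totals ran from 4186063 counts at 12 h to 9899347 counts at 30 h, with 6954153 counts at 0 h, and 9394 genes had a count at 0 h against 10185 at 48 h. Scaled by totals, a level of 10 CPM rested on 42 counts at 12 h, with a 95% interval of 7.23 to 13.56 CPM. At 30 h it rested on 99 counts, with an interval of 8.13 to 12.18 CPM. On that scale a count of 0 allowed up to 0.717 CPM at 12 h and 0.303 CPM at 30 h. The levels below are on the TMM scale, where 1 count was 0.313 CPM at 0 h, 0.229 CPM at 12 h and 0.077 CPM at 30 h. A given TMM level therefore rested on the fewest counts at 0 h. Across genes, Spearman correlations between neighbouring libraries were 0.91 for 0 and 6 h, 0.967 to 0.975 from 6 to 30 h, and 0.927 for 30 and 48 h. The lowest, 0.745, was between 0 and 48 h. Genes are not independent replicates, and no time had a replicate.

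The slope over 0 to 48 h asked which transcripts rose or fell as submerged mycelium gave way to mature conidiophores. brlA, which encodes the zinc finger transcription factor that starts conidiophore formation (contig 14, 308483 to 309781), stood at 0.94 CPM at 0 h and 0.64 CPM at 6 h, from 3 counts each. It stood at 11.5, 67.4, 98.8, 163 and 347 CPM at 12, 18, 24, 30 and 48 h, a fitted rise of 8.73 log2 units ± 1.74 (SE, 7 libraries; edgeR adjusted p = 0.00939). The 48 h level was 369-fold that at 0 h, with a counting interval of 126 to 1792. abaA, which acts downstream of brlA in phialides, rose by 2.79 ± 0.69 (edgeR adjusted p = 0.0213) and wetA, needed for spore wall maturation, by 2.88 ± 0.58 (edgeR adjusted p = 0.00892). Neither followed the course of brlA: abaA went from 15.4 CPM at 0 h to 5.96 CPM at 12 h and 10.01 CPM at 24 h, then to 26.6 and 72.03 CPM at 30 and 48 h, and wetA from 9.09 CPM at 0 h to 8.72 CPM at 24 h, then to 22.5 and 44.3 CPM.

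Of the 7 central regulators 3 rose and 2 fell; adjusted over the list alone, 4 rose and 2 fell. medA, a modifier of conidiophore development, fell by 2.07 log2 units (SE 0.47; edgeR adjusted p = 0.015), from 821 to 200.3 CPM. velB, a velvet family regulator, fell by 1.16 log2 units (SE 0.36; edgeR adjusted p = 0.0463), and its call was lost whenever any 1 library was left out, with upper quartile factors (edgeR adjusted p = 0.111) and without the count filter (0.0547). Scaled by totals alone, the fitted changes were -0.81 for medA (edgeR adjusted p = 0.198) and 0.085 for velB (edgeR adjusted p = 0.915). stuA, at 1054 CPM at 0 h and 1415 CPM at 48 h (edgeR adjusted p = 0.687), and vosA, at 18.5 and 54.8 CPM (edgeR adjusted p = 0.0881), did not pass the test. By totals both rose (1.53 and 2.50; edgeR adjusted p = 0.0404 and 0.0411), so that 5 of the 7 rose and 0 fell on that scale. Without the 48 h library the fitted rise was 0.86 for abaA (edgeR adjusted p = 0.376) and 1.42 for wetA (edgeR adjusted p = 0.133). On a scale of log2 hours plus 6, abaA was not past the test either (2.24; edgeR adjusted p = 0.0958).

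Pigment and spore wall genes rose in 8 of 9 cases; adjusted over the list alone, 9 rose. rodA, the hydrophobin of the rodlet layer (contig 158, 210847 to 211432), had 0 counts at 0 h and 1 count at 6 h, and 16.7, 896, 1395, 3366 and 7561 CPM from 12 to 48 h. Its 48 h level was at least 8045-fold that at 0 h, and its slope passed the test (edgeR adjusted p = 0.0318). dewA, another wall hydrophobin, had 0, 1 and 0 counts up to 12 h and then 4.99, 17.4, 178 and 434 CPM. That was at least 461-fold above 0 h at 48 h, and the slope of dewA passed the test (edgeR adjusted p = 0.00253). ivoA, which acts in conidiophore pigmentation, rose by 6.82 ± 0.86 (edgeR adjusted p = 0.00147), ivoB, a phenol oxidase of the same pathway, by 5.26 ± 1.49 (edgeR adjusted p = 0.0354) and yA, the laccase that turns the yellow spore pigment green, by 3.08 ± 0.66 (edgeR adjusted p = 0.0123). AN6401 did not pass the test (edgeR adjusted p = 0.108), with 0 counts at 0 h, 560 CPM at 18 h and 1129 CPM at 48 h. The median change over the list was 6.82, also with the 3 genes without a count at 0 h set at their bounds. pksP, a pigment polyketide synthase that the fixed list entered as wA, was chosen after its values were seen: it rose from 15.7 to 190 CPM (3.92 ± 0.66; edgeR adjusted p = 0.00449). The calls were lost for yA without the 48 h library (1.44, edgeR adjusted p = 0.159) or on a scale of log2 hours plus 6 (2.49, edgeR adjusted p = 0.058). That of AN0940 was also lost without the 48 h library (1.68, edgeR adjusted p = 0.0588). Those of rodA and ivoB were lost without the 0, 12, 24 or 30 h library (edgeR adjusted p from 0.0519 to 0.0803 for rodA and from 0.0505 to 0.107 for ivoB).

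**Figure D1:**
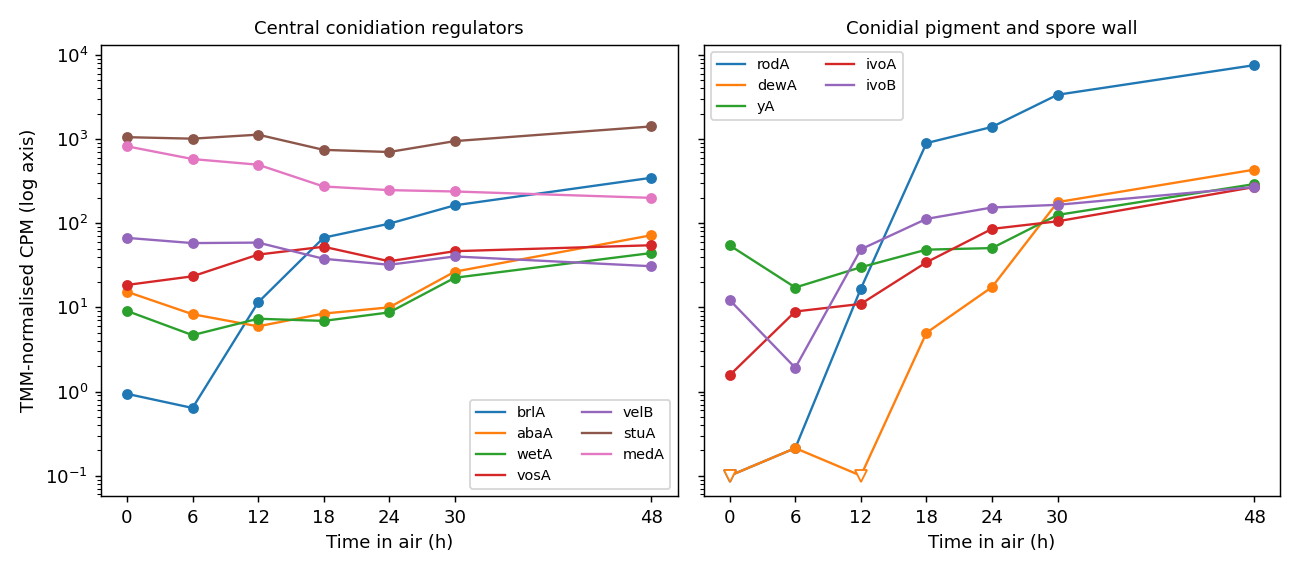
TMM-normalised CPM (log axis) against time in air (h) for the 7 central regulators and for the 5 pigment and wall genes with a symbol, 1 library per time, with open triangles for counts of 0. brlA and rodA climbed from 12 h, while abaA, wetA and yA stood higher at 30 and 48 h than at any earlier time.

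Genes of low oxygen and C2 metabolism fell in 5 of 8 cases and rose in 2, with the same counts adjusted over the list alone. AN4888, entered on the fixed list as the pyruvate decarboxylase gene pdcA, held 2.06% of all counts at 0 h (exact 95% interval 2.05 to 2.07%), the most of any gene there. It fell by 5.13 log2 units (SE 0.69; edgeR adjusted p = 0.00172), from 44943 to 906 CPM. AN2286, entered as the alcohol dehydrogenase gene alcC, fell by 4.45 log2 units (SE 0.60; edgeR adjusted p = 0.00174) and acuF, the phosphoenolpyruvate carboxykinase gene, by 3.30 log2 units (SE 0.81; edgeR adjusted p = 0.0192). The call of acuF was lost without the 0 h library (edgeR adjusted p = 0.0872) or the 30 h library (0.0513). AN8979, entered as alcohol dehydrogenase I (alcA), rose from 0 counts to 153 CPM, at least 163-fold. Its slope passed the test (edgeR adjusted p = 0.00928), though not without the 48 h library (edgeR adjusted p = 0.13). AN0554, entered as aldA, rose from 42.9 to 847 CPM (edgeR adjusted p = 0.0321). It was not past the test without the 24, 30 or 48 h library (edgeR adjusted p = 0.0522, 0.0632 and 0.151). In the autolysis list 1 of 4 genes rose and 0 fell, or 1 and 1 adjusted over the list alone. That gene, AN5558, entered as the protease gene prtA, rose from 83.7 to 7440.0 CPM (5.76 ± 0.74; edgeR adjusted p = 0.00146).

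Among 8 genes listed for repression of conidiation and vegetative growth signalling, 0 rose and 2 fell. Adjusted over the list alone, 2 rose and 2 fell. AN4263, entered as nsdC, had a change of -1.87 (edgeR adjusted p = 0.0168), and of -0.51 by totals (edgeR adjusted p = 0.377). Its call was also lost without the 0 h library (edgeR adjusted p = 0.0516). AN8129, entered as sfgA, and AN2059, entered as velC, did not pass the test (edgeR adjusted p = 0.143 and 0.0805). gpgA, a G protein gamma subunit, fell by 1.98 log2 units (SE 0.48; edgeR adjusted p = 0.019), from 290 to 68.6 CPM; scaled by totals alone the change was -0.65 (edgeR adjusted p = 0.274), and the call was also lost without the 0 h library (-1.22; edgeR adjusted p = 0.0685) or the 30 h library (0.053). By totals 2 of the 8 rose, laeA (2.20; edgeR adjusted p = 0.028) among them, and 0 fell. nsdD stood at 123 and 111 CPM and veA at 136 and 136 CPM at 0 and 48 h, and neither passed the test (edgeR adjusted p = 0.75 and 0.751), nor did sfaD (edgeR adjusted p = 0.489) or laeA (edgeR adjusted p = 0.0778). In the stress tolerance list 1 of 6 genes fell, also adjusted over the list alone. This was treA, a trehalase gene, which went from 173 to 52.2 CPM (edgeR adjusted p = 0.0265) and had a change of -0.13 when scaled by totals (edgeR adjusted p = 0.818). Its call was also lost without the 0, 18, 24 or 30 h library (edgeR adjusted p from 0.051 to 0.0947). catA, a catalase gene, stood at 20.99 and 11.1 CPM (edgeR adjusted p = 0.419) and orlA, which acts in trehalose synthesis, at 353 and 90.9 CPM (edgeR adjusted p = 0.112).

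Of 4 chitin synthase genes chsD, here AN1046 by its reference symbol, rose (1.25 to 6.997 CPM, edgeR adjusted p = 0.0463). csmB, which encodes a chitin synthase with a myosin motor domain, fell (4173 to 418 CPM, edgeR adjusted p = 0.0111). Adjusted over the list alone, 1 rose and 1 fell as well. chsD was not past the test when any 1 library was left out. Of 11 tested sexual development genes 3 rose and 2 fell, with 4 and 2 adjusted over the list alone and 5 and 0 by totals; ppgA, a pheromone precursor, rose from 1.25 to 7.55 CPM (edgeR adjusted p = 0.0394), but did not pass the test without the 0, 6, 12, 24 or 30 h library (edgeR adjusted p from 0.0584 to 0.0887), and steA stood at 133 and 273 CPM (edgeR adjusted p = 0.316). Of 9 cell cycle and septin genes only the septin gene aspE fell (265 to 44.4 CPM; edgeR adjusted p = 0.0192), also adjusted over the list alone; it was not past the test by totals (-0.75; edgeR adjusted p = 0.217), without the 0 h library (-0.97; edgeR adjusted p = 0.0568) or without the 30 h library (edgeR adjusted p = 0.0506). None of the 3 tested light receptor genes passed the edgeR test over all genes or over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. They were fphA, lreB and AN0387. lreA, also on that list, was listed at 0 in all 7 libraries.

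In the list of glucan and cell wall remodelling, 1 of 12 built from reference symbols, 3 of 15 genes rose and 6 fell, or 3 and 9 adjusted over the list alone, 3 and 3 by totals, and 3 and 3 over 6 to 48 h: ags2, an alpha-glucan synthase gene, rose from 7.83 to 147 CPM (4.70 ± 0.90; edgeR adjusted p = 0.00784) while its paralog ags1 fell from 4538 to 366 CPM (edgeR adjusted p = 0.016). In ergosterol synthesis 0 of 17 rose and 4 fell, or 1 and 4 adjusted over the list alone (2 and 1 by totals, 2 and 4 with upper quartile factors), among them erg1, the squalene epoxidase gene, from 814 to 117 CPM (edgeR adjusted p = 0.0038). The nitrate reductase gene niaD and the nitrite reductase gene niiA fell (edgeR adjusted p = 0.0114 and 0.00712), the 2 of 8 genes of nitrate and proline use that did; by totals 1 of the 8 rose and 1 fell. Among heat shock proteins and cochaperones 5 of 9 fell, or 7 adjusted over the list alone, with hsp70 going from 35391 to 1620.3 CPM (edgeR adjusted p = 0.0301); limma-voom called 0 and scaling by totals 2. Without the 0 h library 0 of the 9 were called, also over the list alone, and the change of hsp70 was -1.10 (edgeR adjusted p = 0.119). A single gene fell in each of the lists of proteasome (pre2, of 15), mitochondrial protein import (tom70, of 8), nuclear migration (apsA, of 7) and ribosome assembly (nopA, of 26). By totals 0 genes fell in the first 3 of these lists, and without the 0 h library tom70 and apsA did not pass the test (edgeR adjusted p = 0.0512 and 0.0971). nopA, picked up there by its symbol, is known as an opsin-related protein and not as a ribosome assembly factor. In plant polysaccharide degradation eglD rose and pmeA, a pectin methylesterase gene, fell, of 13 tested. edgeR called 0 of 12 iron and siderophore genes, 0 of 12 peroxins and 0 of 5 autophagy genes. Unadjusted p-values under 0.05 were 1, 3 and 0, DESeq2 called 1, 2 and 0, and limma-voom called 0, 1 and 0. Scaled by totals, 1, 3 and 1 of these genes rose and 0 fell. Except for glucan, ergosterol and heat shock genes, adjusting over the list alone gave the same counts as adjusting over all genes.

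Over all 9703 genes tested, 1028 rose (10.6%) and 1204 fell (12.4%) by edgeR at an adjusted p under 0.05, with median changes of 2.80 and -2.48. Genes with a symbol that had the largest rises after rodA and dewA were ccpA, a conidial wall protein gene, from 1.57 to 588 CPM (10.12 ± 1.23; edgeR adjusted p = 0.00139), brlA, the pigment gene ayg1, from 0 counts to 49.1 CPM, and tmpL, from 0 counts to 117 CPM. encD, fmaF and ugd2 completed the 10 with ivoA. The largest falls were those of zrfA, a zinc transporter gene, from 4578 to 27.0 CPM (-6.70 ± 0.85; edgeR adjusted p = 0.00146), pmcC, a calcium pump gene, pmeA, agd3, a deacetylase gene of exopolysaccharide synthesis, nopA and fhpA, a flavohaemoglobin gene. Scaled by totals alone, 2053 rose and 311 fell, and with upper quartile factors 1244 and 888. Without the 30 h library 639 rose and 691 fell, and without the 48 h library 642 and 768.

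The slope over 6 to 48 h left out the submerged culture and asked for change during growth in air. In the sterigmatocystin cluster, a mycotoxin locus, 12 of 21 genes rose and 0 fell in this fit, 14 adjusted over the list alone, with a median change of 2.82. Over 0 to 48 h 8 rose, also adjusted over the list alone, with a median of 1.84, or 1.63 with the 5 genes without a count at 0 h at their bounds. Levels were low: AN7820, entered on the fixed list as the pathway regulator aflR, stood at 0.31 CPM at 0 h, 0.43 CPM at 6 h (2 counts), 3.16 CPM at 30 h and 19.0 CPM at 48 h (4.88 ± 0.74 over 6 to 48 h; edgeR adjusted p = 0.0029). The rise leaned on the 48 h library: without it AN7820 had a change of 2.75 from 0 h on (edgeR adjusted p = 0.0926, against 5.52 and 0.00223 with it). Of the 8 calls in the cluster over 0 to 48 h, 5 did not pass the test without that library. The other 3, AN7807, AN7809 and AN7810, had at most 3 counts in any other library. That was too few for the count filter, so they could not be tested there and none of the 8 calls remained. yA rose by 4.11 ± 0.37 (edgeR adjusted p = 0.000379), abaA by 3.65 ± 0.47 (edgeR adjusted p = 0.00161), wetA by 3.40 ± 0.42 (edgeR adjusted p = 0.00143) and brlA by 6.42 ± 1.57 (edgeR adjusted p = 0.0281). rodA was not past the test in this fit (edgeR adjusted p = 0.0803). AN5015, entered as the conidiation gene conJ, fell from 495 CPM at 6 h to 23.8 CPM at 48 h (edgeR adjusted p = 0.00258), and stood at 21.6 CPM at 0 h. Of 17 ergosterol genes 7 fell and idi1 rose. hapX, a regulator of the response to low iron, fell from 213 to 41.8 CPM (edgeR adjusted p = 0.00341), as did mirD, and these were the 2 of 12 iron genes called.

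Altogether 977 of 9691 genes rose over 6 to 48 h and 841 fell by edgeR, with median changes of 2.46 and -2.10. The largest rises among genes with a symbol included dewA, ccpA, ayg1, brlA and tmpL again, and also cspA, from 8.73 to 212 CPM, and CweA, from 109 to 1800.4 CPM. The falls added ccg9 (579 to 50.1 CPM) and hem13, a haem synthesis gene (1961 to 210.3 CPM), to zrfA and agd3. Of the genes called over 0 to 48 h, 810 rose in both fits, 678 fell in both and 0 went opposite ways; the fits share 6 libraries, so this overlap is not independent. Scaled by totals, 2157 rose and 379 fell. Without the 12 h library 628 rose and 532 fell, and without the 48 h library 408 and 284.

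Genes that peak inside the course were sought with a curve of hours and hours squared. The 7 upstream activators of brlA gave 0 slope calls by edgeR over all genes and over the list alone, with 1 unadjusted p under 0.05, 1 gene that fell by DESeq2 and 0 by limma-voom. flbB passed the curve test (edgeR adjusted p = 0.0201), with 63.3 CPM at 0 h, 162 CPM at 18 h and 47.0 CPM at 48 h. flbD passed it as well (edgeR adjusted p = 0.0368), with 60.5, 125 and 44.7 CPM at 0, 12 and 48 h. fluG, which acts at the head of the pathway, stood at 141 CPM at 0 h, 511 CPM at 6 h, 239 CPM at 12 h and 78.8 CPM at 30 h, and did not pass the curve test (edgeR adjusted p = 0.231). flbC was highest at 18 h with 209 CPM (edgeR adjusted p = 0.111), flbA went from 179 to 74.1 CPM (edgeR adjusted p = 0.104) and flbE stayed between 21.5 and 26.9 CPM (edgeR adjusted p = 0.944). tmpA stood at 120 CPM at 0 h and 63.8 CPM at 48 h (edgeR adjusted p = 0.191).

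Over all genes 3106 passed the curve test, of which 2031 also had a slope call and 1075 did not. The peak lay at 0 h for 1308 and at 48 h for 1029 of the 3106. Among the 1075 it lay at 0 h for 300, at 18, 24 or 30 h for 166, 145 and 263, at 48 h for 141, and at 6 or 12 h for 17 and 43; of all 3106, the peak lay at 6 h for 93. A curve of this form follows a sharp peak at 6 h poorly. Of the 3 symbol genes highest there over their mean elsewhere, ilv3 (3.63-fold; edgeR adjusted p = 0.0102) passed, and mrsA (4.12-fold; 0.398) and fluG (3.64-fold; 0.231) did not. At 18 h the symbol genes highest over their mean elsewhere were hmgX (2.86-fold), hmgA (2.77-fold) and fahA (2.16-fold), all of the breakdown of aromatic amino acids; hmgX and hmgA passed the curve test (edgeR adjusted p = 0.00371 and 0.0124) and fahA did not (0.128). At 24 h they were sakA, grpE and ags2, at 30 h mfsA, dewA and nar1, and at 48 h optB, an oligopeptide transporter gene at 237 CPM (16.6-fold), dewA and ccpA. At 12 h they were sidD, sit1 and fdh. This ranking does not require a peak at the time named: sidD was higher at 6 h, and ags2 and dewA at 48 h. Among the genes of 12, 24 and 30 h, sidD, fdh, sakA, grpE and nar1 did not pass the curve test (edgeR adjusted p = 0.72, 0.308, 0.0973, 0.086 and 0.654). The others did. The curve called 4671 genes with totals alone, 2031 without the 18 h library and 1640 without the 48 h library.

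**Figure D2:**
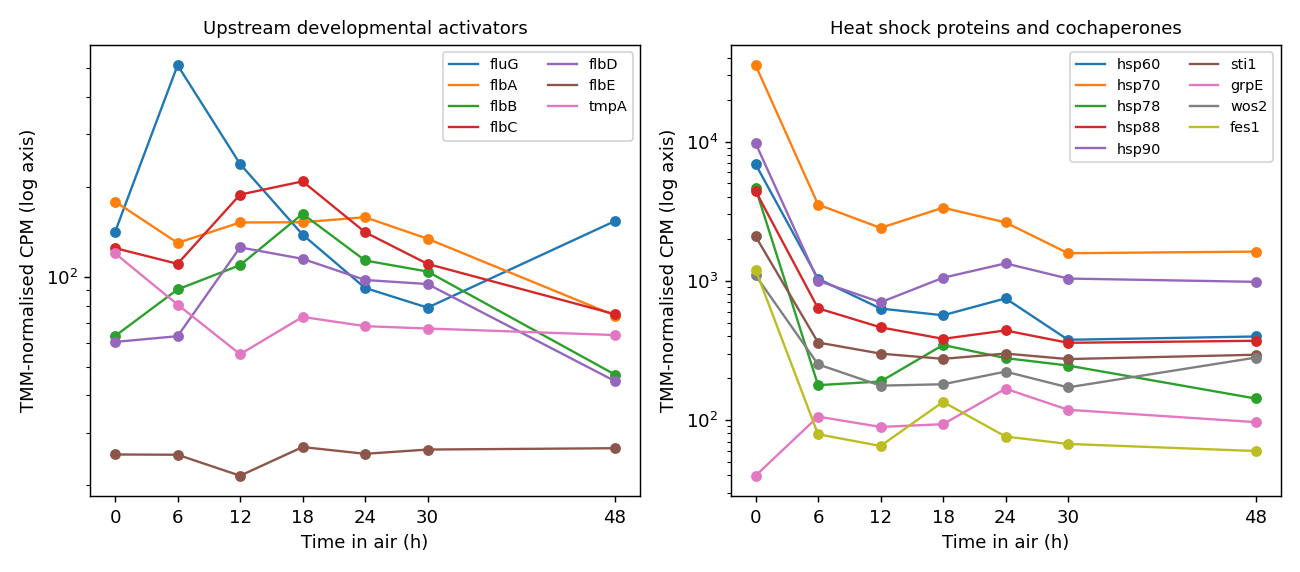
TMM-normalised CPM (log axes) against time in air (h) for the 7 upstream activators and for 9 heat shock and cochaperone genes, 1 library per time. fluG was highest at 6 h (511 CPM), and 8 of the 9 chaperone genes were highest at 0 h, the exception being grpE.

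Between the submerged culture at 0 h and the filters at 6 h, iron uptake genes were higher and heat shock genes lower. sidI, a siderophore synthesis gene, had 3 counts at 0 h and 709 counts at 6 h, a 161-fold difference with a counting interval of 54.7 to 780.3. mrsA, a mitochondrial iron carrier gene, was 23.7-fold higher (16.6 to 35.1) and sidD, a siderophore synthetase gene, 13.7-fold higher (11.4 to 16.5); mirD, sidJ and sit2, also of siderophore metabolism, were among the 10 symbol genes with the largest folds, with ltpA, gmdB, crnA and gcy1. Of 11 iron genes with at least 10 CPM, 5 were at least 4-fold higher. Their median of 1.59 log2 units lay at the 100th percentile of random lists. Heat shock genes were at least 4-fold lower in 8 of 9 cases, with a median of -2.80 at percentile 0. Scaled by totals, 4 of the 9 were at least 4-fold lower, and the median was -1.86. Both percentiles treat genes as independent draws, while camera's estimated correlation between genes was 0.404 for the iron and 0.569 for the heat shock list. They may thus be too extreme. hsp78 was 26.0-fold lower (24.2 to 27.9), hsp70 10.04-fold lower (9.88 to 10.21), hsp90 9.72-fold lower (9.43 to 10.03) and the cochaperone fes1 15.2-fold lower (13.7 to 17.0), beside vip1, zpr1, sskA, met16, cbpA and fbp1.

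Proteasome genes, with a median of 0.27 at percentile 98.6, and ribosome assembly genes, with 0.72 at percentile 96.7, stood high among random lists as well. The same limit applies to them, with estimated correlations of 0.573 and 0.414. Low percentiles of 0.2, 0.4 and 4.4 rested on only 6 of the 21 sterigmatocystin genes (median -1.48), 8 of 16 plant polysaccharide genes (-1.16) and 4 of 9 pigment and wall genes (-1.12). These were the members with at least 10 CPM in the higher library, a filter that the 0 h level itself partly decides, so they do not stand for the whole lists. The remaining 17 lists lay between 12.2 and 92.4. By size alone 266 of 7012 genes were at least 4-fold higher at 6 h and 454 at least 4-fold lower, and with totals in place of TMM these counts were 922 and 136. Among genes known only by identifier, AN7521 was highest above 0 h, with 7 counts at 0 h and 8102 at 6 h, followed by AN0531, with 5 and 3997. Furthest below were AN2035, 150-fold (89.1 to 275), and AN10447, with 137 counts at 0 h and 0 at 6 h, at least 67.2-fold.

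From 6 h on, neighbouring libraries differed far less. At least 4-fold higher and lower at the later time were 101 and 27 genes from 6 to 12 h, 30 and 4 from 12 to 18 h, 16 and 0 from 18 to 24 h, 23 and 42 from 24 to 30 h and 115 and 151 from 30 to 48 h, where the gap was 18 h instead of 6 h. ivoB was 25.6-fold higher at 12 h than at 6 h (13.2 to 56.8) and brlA 17.95-fold (5.80 to 90.0). rodA was 53.55-fold higher at 18 h than at 12 h (42.5 to 68.4). dewA was 10.2-fold higher at 30 h than at 24 h (8.43 to 12.5), while abaA was 2.66-fold (2.02 to 3.54) and wetA 2.58-fold (1.93 to 3.52) higher over that step. By totals the 24 to 30 h counts were 38 and 39. No pair of times has a replicate, so these sizes describe pairs of libraries and not the times.

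**Figure D3:**
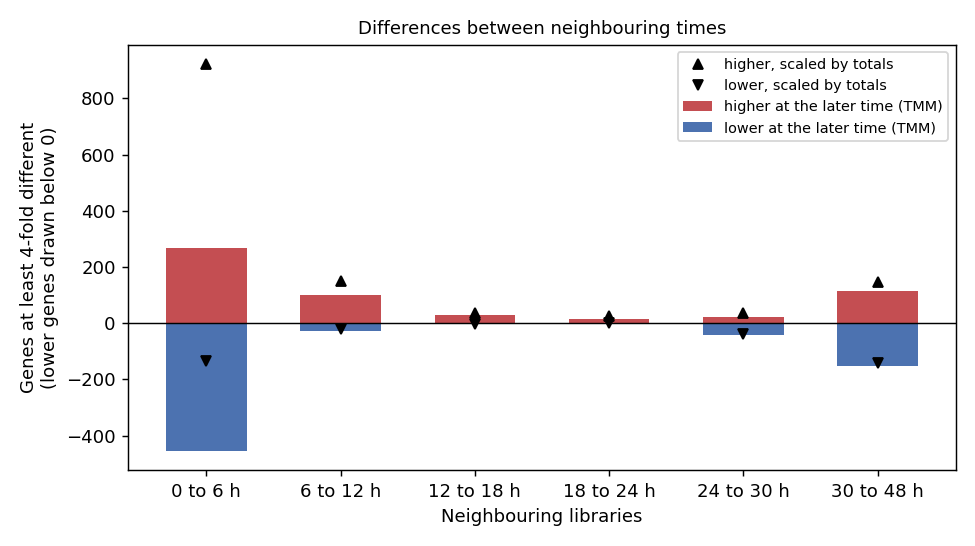
Bars give the number of genes at least 4-fold higher (above 0) or lower (drawn below 0) in the later of 2 neighbouring libraries with TMM, and triangles the same counts by library totals. The 0 to 6 h step held 266 higher and 454 lower genes with TMM, more than any later step, and 922 and 136 by totals.

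Gene lists were then tested for their slope over 0 to 48 h, with camera against the other genes and with fry on their own. Pigment and spore wall genes (camera adjusted p = 6.16e-05) and the sterigmatocystin cluster (camera adjusted p = 0.00172) were called higher with a preset correlation, and 0 of 24 lists were called lower. With an estimated correlation neither call held (adjusted p = 0.527 and 0.693 with an estimated correlation). fry, which asks whether a list's genes move one way on balance, gave an adjusted p of 0.0102 for pigment and wall genes, 0.0767 for the cluster and 0.00229 for a fall of the low oxygen and C2 genes, which camera did not call (adjusted p = 0.0727). Without the 48 h library, or with the rank order of the times, the cluster was not called. Heat shock genes were called lower without the 12 h library, heat shock and low oxygen genes without the 48 h library, and these 2 lists and glucan remodelling by totals. The median and the camera direction differed in sign for autolysis (median -0.21, mean 1.02), iron (-0.03 and -0.10) and mitochondrial import (0.04 and 0.04), and camera and fry differed in direction for plant polysaccharide degradation (0 and -0.19).

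**Figure D4:**
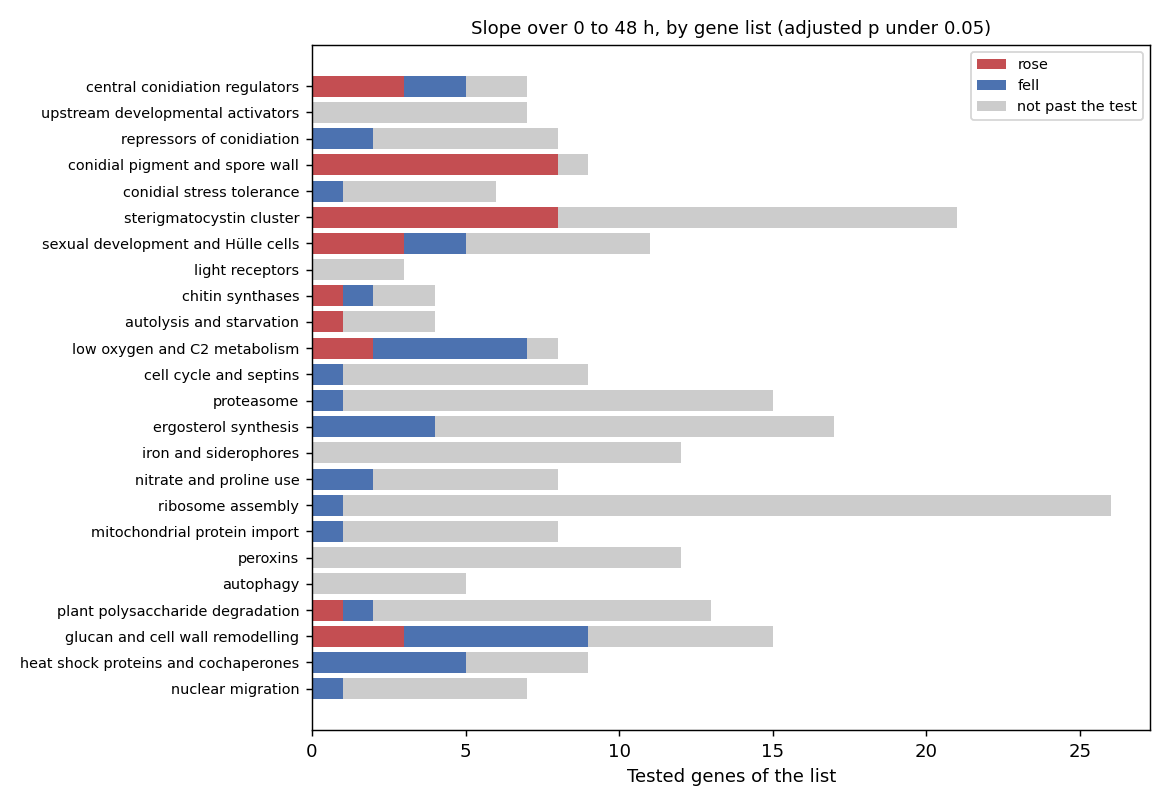
Bars count, for each of 24 lists, the tested genes that rose, fell or did not pass the edgeR slope test over 0 to 48 h at an adjusted p under 0.05. In the pigment and spore wall list 8 of 9 rose, and in the low oxygen and C2 list 5 of 8 fell and 2 rose.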

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

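Scaling by totals alone was chosen for the slope, curve and list tests only after the data had been seen; the other settings were set earlier. No gene called in the 0 to 48 h or 6 to 48 h fit was called in the opposite direction under any setting, but the counts depended on scaling and on single libraries. With totals alone 2053 genes rose and 311 fell over 0 to 48 h (1028 and 1204 with TMM), 2157 rose and 379 fell over 6 to 48 h (977 and 841), 4671 had a curved or straight course (3106), and 922 were higher and 136 lower at 6 h than at 0 h (266 and 454). Between 18 and 24 h 27 differed by totals (16), and 5 lists were called (2). The slope of velB turned from -1.16 to 0.085. The TMM and total scales differ by construction, as the TMM factors climbed from 0.459 at 0 h through 0.878 at 6 h to 1.395 at 48 h. Which scale is nearer to the cells' RNA content was not tested.

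Leaving out each library in turn gave 639 to 1112 rising and 691 to 1205 falling genes over 0 to 48 h, 408 to 1022 and 284 to 973 over 6 to 48 h, and 1640 to 4396 for the curve. The cause of these ranges was not tested. DESeq2 called 1285 falling genes over 6 to 48 h, against 841. Camera with an estimated correlation called 0 lists and the rank order of the times 1, against 2.

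Counts by size moved with the rule, as its construction implies. With a pseudocount of 5 CPM, 141 genes were higher at 6 h than at 0 h, and the steps from 6 to 12 h, 12 to 18 h, 18 to 24 h, 24 to 30 h and 30 to 48 h held 45, 14, 6, 30 and 116 genes, in place of 128, 34, 16, 65 and 266. With a CPM of 1 in the higher library the first 3 of these steps held 320, 89 and 30. A 2-fold limit gave 1153 higher and 1451 lower genes at 6 h, then 648, 427, 308, 392 and 1331 per step, and an 8-fold limit 111 and 137, then 35, 10, 0, 11 and 35.

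Among 144 named genes, 84 past the test, 2097 values under other settings kept the state of the gene, called or not called, 115 were weaker, 57 stronger and 1 reversed, and genes past no test changed sign in 63 cases. Genes removed by the stricter filter, such as chsD, have no value there. No paired analysis was possible because each time had 1 library. Alternatives for values that are not counts did not apply and were not run.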

Other observations

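The tests of handling, of scaling for abaA, wetA and yA, and of neighbouring genes were chosen only after the results had been seen; the predictions for library order, gene length, conidial RNA and heat shock scaling were written before those tests were run, for patterns already seen.

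Some genes that rose over 0 to 48 h lay side by side among the tested genes, 48 of the 1028 in runs of at least 5. Untested genes lying between them were passed over. The longest run, AN9245 to AN9256 on contig 169 (26773 to 53996), held 13 genes with a median change of 9.75 log2 units, from a median of 0 to 128 CPM. AN8375 to AN8381 on contig 149 held 7 genes (0 to 118 CPM) and AN3225 to AN3230 on contig 52 held 6 (3.29 to 115 CPM). All 13 and all 7 genes of the former runs also rose over 6 to 48 h, against 1 of the 6. Among falling genes, AN2030 to AN2038 on contig 31 held 9, with a median change of -6.00 and levels of 447 CPM at 0 h and 2.39 CPM at 48 h. Its level was 14.3 CPM at 6 h already, and without the 0 h library only 3 of the 9 genes were called. AN7873 to AN7884 on contig 132 held 12 falling genes (39.8 to 4.49 CPM), 7 of them also called without the 0 h library. There were 7 runs of at least 5 neighbouring genes that rose, against at most 2 in any of 2000 shuffles of the calls over the gene order, and 10 runs of genes that fell, against at most 3. The permutation p for both was 5e-04, the smallest that 2000 shuffles allow. The shuffles take no account of overlapping genes or near-identical paralogs, which these counts cannot separate.

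The genes past the slope test over 0 to 48 h were set against chance order of the libraries and gene length. In 2 of 100 orders, the true one included, as many genes passed, and the other order, with 2718 genes, had a rank correlation of 0.96 with the true one. The median of the other orders was 0 genes. Across genes, slope and span had a Spearman rho of -0.082, with 11.5% rising among the 3235 genes of shortest span and 9.8% among the 3234 of longest span, while the falling shares ran the other way, 10.4% and 13.5%, so neither order nor length is likely to give the calls.

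Heat shock genes were lower at 6 h than at 0 h with TMM (median -2.80) and also by totals (median -1.86, SD 1.70 over 9 genes). A change of scale moves all genes alike, so this shows only that using totals in place of TMM does not remove the difference. The 9 genes are not independent replicates. Handling of the 0 h filters before freezing could be the source, as could growth in the submerged culture. With 1 library at 0 h the data cannot separate these.

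abaA, wetA and yA were higher at 0 h than at 6 h with TMM. Conidial RNA of the 48 h make-up that was in the submerged culture and gone by 6 h is unlikely to explain it. Over 117 genes at least 20-fold higher at 48 h than at 6 h, the median level at 0 h was 0.0045 of that at 48 h. For abaA, wetA and yA it was 0.213, 0.205 and 0.187. Of the 117 genes, 10 stood above 0.05 of their 48 h level at 0 h. As these genes were chosen as high at 48 h and low at 6 h, spore RNA of another make-up, or still present at 6 h, was not covered. abaA and wetA were 8.68- and 9.46-fold higher at 48 h than at 6 h, so they were not among the 117. By totals the ratio of yA at 0 h to 6 h was 1.65 (1.26 to 2.18), which scaling of the 0 h library does not remove. For abaA (0.967, 0.622 to 1.51) and wetA (1.01, 0.563 to 1.85) it does: 0 of these 2 genes had a ratio with an interval above 1, so scaling of the 0 h library may account for them.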
